A study of Mus musculus with 9 samples.

How the data were processed

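Total RNA of sorted splenic T cells was sequenced in 9 libraries, 3 from healthy mice, 3 from syngeneic and 3 from allogeneic transplant recipients. Per the labels' protocols, T cells were enriched with a pan-T-cell kit and then sorted as live CD3+ CD45.2+ cells, RNA was treated with DNase, and stranded libraries were made from 100 ng of RNA with ribosomal RNA depletion. Each library was grouped by the transplant type in its label. The strain tag of all 9 libraries names the syngeneic recipient strain, in conflict with the protocols' allogeneic recipients and with the C57BL/6 mice of the naive titles, and was not used. Transplant replicates were pools of different recipients, per the series' design text, so that their spread is that between pools. Whether naive libraries were pooled is not given in the sources used here, and their spread is that between libraries.

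The authors deposited 1 table of raw read counts per gene for all libraries, with Ensembl gene identifiers. FastQC 0.11.3, TopHat2 2.0.13, Bowtie2 2.2.1, HTSeq 0.6.1 and the GRCm38 build are named per the submitters' processing notes. The annotation release, the strand setting of the counting, read trimming and any filter are not given in the sources used here. The table holds 29229 genes and no line without a gene, and 541 genes have no count in any library. Gene symbols, biotypes and coordinates came from GENCODE M21, which matched 29014 identifiers. The 215 identifiers without a match held 0.053 to 0.099% of the counts of a library and kept their place in library sizes and tests. Since the strand setting is not known, reads of overlapping genes on opposite strands may be mixed, and genes annotated as antisense held 0.093 to 0.159% of counts. Near-identical copies, such as globin, histone, ribosomal protein, Klra and T-cell receptor genes, can share reads, and the handling of reads with several alignments is not given in the sources used here. Total RNA libraries also hold unspliced and noncoding RNA, and Gm26917 and Gm42418, read as a ribosomal RNA locus from background knowledge, took part of the counts of each library. Depth over other genes was therefore below the total.

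The tests fitted the unit of the deposited counts. Genes were kept by edgeR's filterByExpr by group, which left 19609, and scaled by TMM. Changes were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest) in 1 model of all 9 libraries with the group as the only term, so that the 3 groups shared an estimate of the spread. The common biological coefficient of variation was 0.193 and the median prior degrees of freedom 5.17. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM values used TMM-scaled library sizes. A fold against a group without counts was computed against 3 counts over the group, as a lower bound. Gene lists, 41 of them with at least 3 measured members, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The lists covered T-cell states and lineages, signalling, metabolism, the cell cycle and markers of other cells of the spleen and marrow. Per list, the members passing the gene test were counted with p-values adjusted over all genes and over the list alone. The log2 ratio of Cd8a to Cd4 counts and the Shannon entropy of T-cell receptor beta variable segment counts were compared per library with exact 2-sided permutation tests, in which 3 against 3 libraries cannot go below p = 0.1. For the entropy each library was thinned to 22104 counts over 21 segments in 200 draws.

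The overlap of the changes against naive libraries was set beside 20 simulations of unchanged groups that shared the naive libraries. Replicates were compared before averaging, by a chi-square over genes with a summed count of at least 20, and none were alike within sampling noise. The gene test was tested on simulated counts with each gene's mean over all 9 libraries and the library sizes of the data. In these counts 200 of 19609 genes, drawn from those above a minimum mean level, were changed in the allogeneic group, 100 at each fold. The test recovered 26% of the genes changed 1.5-fold and 75% of those changed 2-fold. The sign was right for 97% and 100%, and the median log2 sizes were 0.59 and 1.04. The test called 111 genes, of which 9% were false, and 2 genes in a simulated comparison without change. Camera called 0 of 40 unchanged lists on simulated data. Simulated genes varied independently of each other, so this does not test false calls of lists whose genes vary together. With 200 changed genes, a change of 1.5-fold was often missed in the simulation. The real comparisons called 8213 to 11315 genes, which makes the adjusted threshold less strict. These shares of recovery therefore do not carry over to them.

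The groups, comparisons, tests, lists, named-gene rule and other settings were chosen before the data were examined. Named genes were, per comparison, up to 12 genes per direction with the largest fold change among called genes at 5 CPM or more with no overlap of the groups, without predicted names and receptor segments. To these came up to 4 members per list with the smallest adjusted p and up to 2 against the majority, 17 T-cell genes named in every comparison, and up to 4 long noncoding RNAs per direction. Some genes chosen in this way are not reported here. Gm26917, Gm42418, Klra8 as a gene without counts, Clec9a, Igkc and the single receptor segments were chosen after their values were seen. The other settings were DESeq2 size factors, library sizes alone, DESeq2 1.42.0, limma-voom, no filter and a stricter filter, a fit of the 2 groups alone, a block for the replicate number, a minimum fold change, other list tests, Cd8b1, alpha segments, no thinning and leaving out each library. Settings added after seeing the data are named as such where they are given. Computations used R 4.3.3, python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.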

Results

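Donor T cells were profiled by RNA sequencing in mouse hematopoietic stem cell transplantation, the procedure in which lethally irradiated recipients are rescued with donor bone marrow. Live CD3+ CD45.2+ cells, where CD45.2 is the leukocyte allele carried by the donors, were sorted from the spleen. Libraries came from healthy non-transplanted mice (naive) and from recipients killed 7 days after a syngeneic or an allogeneic transplant, with 3 libraries per group. Each transplant library was a pool of 2 to 4 recipients, and the labels describe the libraries of a group as independent biological replicates. All mice were female and 8 to 12 weeks old. Syngeneic recipients were CD45.1 mice of the donors' H-2b major histocompatibility type. Allogeneic recipients carried H-2d, so that donor T cells met foreign major histocompatibility molecules, the setting of graft-versus-host disease. The transplant groups differed in more than the antigen. Syngeneic recipients had 9.5 Gy and 8500000 T cells, and allogeneic recipients had 8 Gy and 1000000 T cells. Both had 5000000 T-cell-depleted C57BL/6 marrow cells, whose progeny also carry CD45.2.

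The total count per library was 122100000 ± 14000000 (mean ± SD, n = 3) in naive, 115500000 ± 12800000 in syngeneic and 132900000 ± 38600000 in allogeneic libraries, with a range of 103953932 to 176678189 over the 9 libraries. A count of 3 over the 3 libraries of a group is worth 0.00802 counts per 1000000 (CPM) in naive, 0.00873 in syngeneic and 0.00761 in allogeneic libraries, and covers counting error only. Gm26917 and Gm42418, neighbouring annotated RNAs on chromosome 17 (39843013 to 39846341 and 39846958 to 39848788 of GRCm38) that are taken here, without a test, to collect ribosomal RNA reads, took 17.7 ± 1.65% of naive, 20.9 ± 1.53% of syngeneic and 11.4 ± 5.11% of allogeneic counts. Their share was 17.2% in allogeneic library 1 and 9.06% and 7.87% in the other allogeneic libraries. Replicates of a group correlated at Pearson r of 0.993 to 0.999 across genes and differed by more than sampling noise, with a chi-square of 22.5 to 362 per degree of freedom. The first principal component of the 2000 most variable genes held 67.5% of their variance and placed naive libraries at -113.9 to -105.74 and transplant libraries at 11.57 to 79.26. The second held 26.5% and placed syngeneic libraries at -72.21 to -52.77 and allogeneic libraries at 49.51 to 60.13. CPM values are given as mean ± SD over the 3 libraries of a group, log2 fold changes with their standard error (SE), and adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test ("edgeR adjusted p") or from limma's camera test over 41 gene lists ("camera adjusted p").

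The comparison of allogeneic with syngeneic libraries asks how donor T cells that met foreign recipient antigens differed from donor T cells in a genetically matched recipient. Genes of killing and of checkpoint receptors were higher in the allogeneic libraries, and genes of the naive state were lower. Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), which encodes the cytolytic protease granzyme B, stood at 1560 ± 85.7 CPM in allogeneic and 93.4 ± 23.8 CPM in syngeneic libraries, against 4.50 ± 1.22 CPM in naive libraries. Its log2 fold change was 4.07 ± 0.22 (edgeR adjusted p = 1.28e-07). Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), which encodes the inhibitory receptor PD-1, rose from 15.1 ± 0.676 to 339 ± 22.7 CPM (log2 fold change 4.49 ± 0.11, edgeR adjusted p = 1.15e-09). Ccr7 (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), the chemokine receptor of naive and central memory T cells, fell from 198 ± 43.3 to 13 ± 2.05 CPM (log2 fold change -3.93 ± 0.17, edgeR adjusted p = 4.45e-08). Of 19609 genes tested, 4766 were higher and 4066 lower in allogeneic libraries. At least 2-fold changes were found for 3816 of these, 1533 higher and 2283 lower, so that the majority turned. The values of the 6 libraries did not overlap between the groups for 10815 genes (55.2%), where chance gives 10%.

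**Figure D1:**
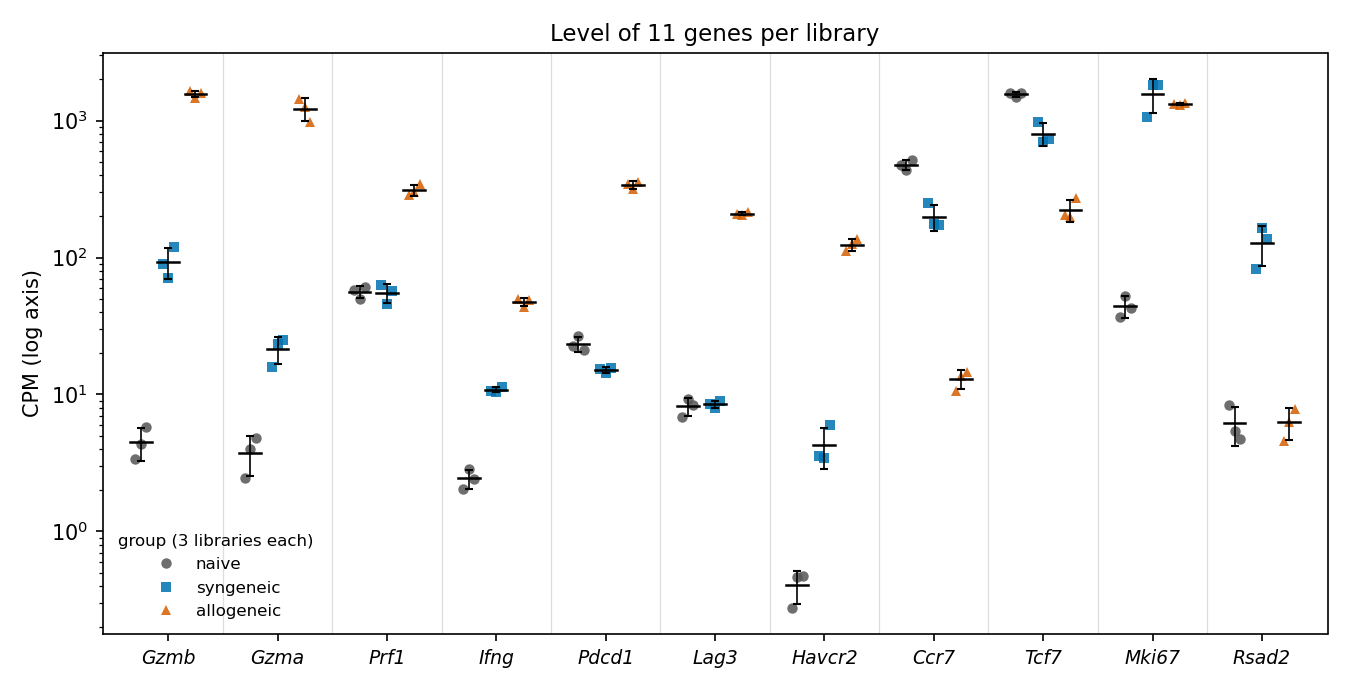
Level of 11 genes in each library in CPM on a log axis, with naive libraries as circles, syngeneic as squares and allogeneic as triangles; black lines are the mean and SD of 3 libraries. Gzmb was at 1560 CPM in allogeneic, 93.4 CPM in syngeneic and 4.50 CPM in naive libraries.

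In the cytotoxic effector list, 14 of 17 genes rose and 2 fell (median log2 fold change 2.13, camera adjusted p = 4.95e-07, and adjusted p = 0.34 with an estimated correlation). Gzma, the granule protease granzyme A, rose from 21.4 ± 4.72 to 1220 ± 232 CPM, and Prf1, the pore-forming perforin, from 55.4 ± 8.62 to 311 ± 28.4 CPM. Serpinb9, an intracellular inhibitor of granzyme B, rose by a log2 fold change of 3.01 ± 0.10 (edgeR adjusted p = 5.18e-09). The members that fell were Gzmm, which encodes granzyme M (-1.78 ± 0.14), and Tnf, which encodes the inflammatory cytokine TNF (-0.79 ± 0.14). In the type 1 program, 15 of 18 genes rose and 1 fell (median 1.63, camera adjusted p = 1.03e-07, and adjusted p = 0.257 with an estimated correlation). Ifng, the gene of interferon gamma, rose from 10.8 ± 0.446 to 47.4 ± 3.18 CPM and Tbx21, which encodes the type 1 transcription factor T-bet, from 94.3 ± 19.6 to 281 ± 33.6 CPM. The effector regulators Id2 (2.60 ± 0.08) and Prdm1 (2.87 ± 0.13), which encodes Blimp-1, also rose, and Eomes, a relative of T-bet, was the member that fell (160 ± 21.3 to 68.2 ± 13.9 CPM, -1.23 ± 0.14). In the inhibitory receptor and exhaustion list, 13 of 17 genes rose and 1 fell (median 1.61, camera adjusted p = 3.86e-07, and adjusted p = 0.257 with an estimated correlation). Lag3 rose from 8.51 ± 0.492 to 210 ± 6.21 CPM, Tigit from 11.1 ± 0.973 to 199 ± 13.5 CPM and Havcr2, which encodes TIM-3, from 4.30 ± 1.43 to 124 ± 12.6 CPM. Tox, a transcription factor needed for the exhausted T-cell state, rose by 1.31 ± 0.08 on the log2 scale, and Nr4a1, an early gene of antigen receptor signalling, was the member that fell (-0.39 ± 0.10, edgeR adjusted p = 0.00974). The counts of these lists were the same when adjusted over the list alone.

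Genes of several helper T-cell programs were also higher in allogeneic libraries, where Cd4 was higher too, by 1.11 ± 0.13, and the Cd8a to Cd4 ratio was 0.92 against 2.96 in syngeneic libraries. Members also in another list were 2 of 10 type 2, 3 of 9 follicular helper and 6 of 15 regulatory genes. So were 7 of 16 costimulation and 2 of 16 homing genes, and the lists are therefore not fully separate. In the type 2 program, 9 of 10 genes rose and 1, the chemokine receptor gene Ccr4, fell (median 3.13, camera adjusted p = 9.1e-06, and adjusted p = 0.257 with an estimated correlation). The cytokine gene Il13 was at 8.54 ± 1.01 CPM in allogeneic and 0.136 ± 0.0653 CPM in syngeneic libraries. Gata3, the type 2 master regulator, rose from 82.0 ± 5.31 to 288 ± 20.3 CPM and Maf from 22.4 ± 2.87 to 182 ± 21.7 CPM. In the follicular helper list, 8 of 9 genes rose, among them the costimulator gene Icos (2.52 ± 0.09) and Tox2 (2.33 ± 0.15), with a median of 2.33 (camera adjusted p = 4.16e-05, and adjusted p = 0.257 with an estimated correlation). In the regulatory T-cell list, 8 of 15 rose and 3 fell (median 1.08, camera adjusted p = 0.00912, and adjusted p = 0.372 with an estimated correlation). The members that rose included Il2ra, the interleukin-2 receptor alpha chain (2.19 ± 0.11), and Nrp1 (2.92 ± 0.15), both also made by activated effector cells. Foxp3, which defines the regulatory lineage, was at 28.0 ± 5.39 CPM in allogeneic and 26.9 ± 4.19 CPM in syngeneic libraries (edgeR adjusted p = 0.75), and its log2 fold change turned to -0.10 without allogeneic library 2 and to -0.02 without syngeneic library 1. In the costimulation and activation list, 12 of 16 rose and 3 fell, or 13 and 3 adjusted over the list alone (median 1.02, camera adjusted p = 6.76e-05, and adjusted p = 0.257 with an estimated correlation). Tnfrsf9, which encodes 4-1BB, rose by 2.06 ± 0.12, while the growth regulator Myc (-1.18 ± 0.10) and the transferrin receptor gene Tfrc (-2.59 ± 0.33) fell. The homing and adhesion list had 12 of 16 genes higher and 3 lower (median 1.22, camera adjusted p = 0.000653, and adjusted p = 0.257 with an estimated correlation). The chemokine receptor genes Cxcr6 and Cx3cr1 rose by 3.20 ± 0.10 and 3.90 ± 0.20, and Itgae, the integrin CD103, fell by 1.34 ± 0.17. Adjusted over the list alone, the counts of the other lists here were the same.

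Genes of the naive state, of the response to type I interferon and of immediate early transcription were lower in allogeneic libraries. In the naive and quiescence list, 16 of 20 genes fell and 1 rose (median -1.30, camera adjusted p = 1.03e-07, and adjusted p = 0.372 with an estimated correlation). Tcf7 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014), which encodes TCF-1, fell from 804 ± 151 to 224 ± 41.2 CPM, and Il6ra from 214 ± 29.7 to 21.6 ± 2.58 CPM. Il7r, the interleukin-7 receptor, was the member that rose (0.42 ± 0.15, edgeR adjusted p = 0.0357), and its edgeR adjusted p was 0.0671 without allogeneic library 1, 0.138 without allogeneic library 2, 0.0619 without syngeneic library 1 and 0.111 without syngeneic library 3. Of 23 type I interferon response genes, 16 fell and 1, the RNA sensor gene Ifih1, rose (median -0.72, camera adjusted p = 5.97e-05, and adjusted p = 0.448 with an estimated correlation). Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), the antiviral protein viperin, fell from 128 ± 42 to 6.27 ± 1.65 CPM and was at 6.16 ± 1.93 CPM in naive libraries. Isg15 and Usp18 fell by 1.66 ± 0.13 and 2.08 ± 0.17 on the log2 scale. The erythroid, macrophage and B-cell lists, given below, also had more genes lower than higher, and the cells that made these transcripts were not identified. Of 12 immediate early genes, which cell dissociation also induces, 10 fell and none rose (median -1.47, camera adjusted p = 0.00135, and adjusted p = 0.372 with an estimated correlation), with Fos at -2.44 ± 0.26 and Jun at -2.03 ± 0.18. The counts of these lists were the same when adjusted over the list alone.

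Of 6 metabolic lists 4 were called by camera, all of them higher, and 2 were not called. Of 18 glycolysis genes, 14 rose and 2 fell (median 0.63, camera adjusted p = 0.000464, and adjusted p = 0.488 with an estimated correlation), with the glucose transporter gene Slc2a3 at 1.49 ± 0.08 and the hexokinase gene Hk2 at 0.95 ± 0.10. Of 18 fatty acid oxidation genes, 14 rose, or 15 adjusted over the list alone, and none fell (median 0.58, camera adjusted p = 2.69e-05, and adjusted p = 0.372 with an estimated correlation). Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose by 1.71 ± 0.14. Of 24 oxidative phosphorylation genes 14 rose and none fell (median 0.37, camera adjusted p = 0.00141, and adjusted p = 0.644 with an estimated correlation). Of 18 genes of the TCA cycle 10 rose and 1, the isocitrate dehydrogenase gene Idh2, fell (median 0.34, camera adjusted p = 0.0312, and adjusted p = 0.644 with an estimated correlation), a call lost without allogeneic library 1 (camera adjusted p = 0.0787) or syngeneic library 2 (0.0744). Of 15 one-carbon and amino acid supply genes 2 rose and 6 fell (median -0.30, camera adjusted p = 0.106, and 0.0339 without allogeneic library 1), and of 19 cholesterol synthesis genes 8 rose and 2 fell (median 0.17, camera adjusted p = 0.197). Of 20 mitosis genes 8 rose, or 7 adjusted over the list alone (median 0.36, camera adjusted p = 0.0243, and adjusted p = 0.644 with an estimated correlation), and this call was lost without allogeneic library 1 (camera adjusted p = 0.102) or syngeneic library 1 (0.13). Mki67 was at 1320 ± 25.1 CPM in allogeneic and 1570 ± 433 CPM in syngeneic libraries (edgeR adjusted p = 0.316), and its log2 fold change was -0.45 without syngeneic library 1 (edgeR adjusted p = 0.0158). Of 20 DNA replication genes 4 fell by edgeR's quasi-likelihood test, the count also at an unadjusted p under 0.05 and by limma-voom, while DESeq2 called 2 and none passed adjusted over the list alone. Their camera adjusted p was 0.59, with a median of 0.01, a mean of -0.05 and a camera direction of lower. That median was -0.01 with library sizes alone as scaling. The signs also differed for 3 lists that were not called, the unfolded protein response (median 0.26, mean -0.06, camera higher), the interferon gamma response (-0.02, -0.10, higher) and NK-cell genes (0.17, -1.07, higher).

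Markers of other cell types differed between the transplant groups as well. Of 14 erythroid genes 13 were lower in allogeneic libraries and none higher (median -7.06, camera adjusted p = 7.19e-08, and adjusted p = 0.372 with an estimated correlation). Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096), an adult beta-globin gene whose reads its near-identical paralog can share, was at 1450 ± 481 CPM in syngeneic and 3.76 ± 1.7 CPM in allogeneic libraries. Slc4a1, the red cell anion exchanger band 3, was at 1270 ± 588 and 7.26 ± 4.46 CPM, and Alas2, the first enzyme of erythroid heme synthesis, at 283 ± 109 and 0.788 ± 0.424 CPM. Tfrc, listed above with activation genes and also abundant in erythroid precursors, moved with them. Of 15 macrophage and monocyte genes 11 fell and 2 rose (median -2.21, camera adjusted p = 0.0854, and 0.00432 without syngeneic library 1). Csf1r, the macrophage growth factor receptor, was at 13.4 ± 8.19 CPM in syngeneic and 1.76 ± 0.502 CPM in allogeneic libraries. Lgals3, which encodes galectin-3 and is also made by activated T cells, rose from 21.5 ± 5.33 to 557 ± 39.4 CPM. Of 15 B-cell genes 7 fell and 1, the immunoglobulin heavy chain gene Ighm, rose (median -0.89, camera adjusted p = 0.0129, and adjusted p = 0.583 with an estimated correlation). The edgeR adjusted p of Ighm was 0.0521 without allogeneic library 3. Of 7 plasma cell genes 3 rose (median 1.05, camera adjusted p = 0.0183, and adjusted p = 0.437 with an estimated correlation), among them Irf4 and Txndc5, which activated T cells also express. None of 15 neutrophil genes passed by edgeR's quasi-likelihood test (median -0.14, camera adjusted p = 0.958), and the count was also 0 at an unadjusted p under 0.05, by DESeq2 and by limma-voom. Of 11 NK-cell genes 5 rose and 4 fell (median 0.17, mean -1.07, camera adjusted p = 0.809). The median was 0.17 also with Klra8, which had no count in allogeneic libraries and was at least 68.5-fold lower there, at its bound. The mean includes the fitted log2 fold change of Klra8, -9.01, at 0.522 CPM in syngeneic libraries. Reads of the Klra genes can be shared among paralogs. The counts of these lists were the same when adjusted over the list alone.

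Of the genes outside the lists, Gldc, the glycine decarboxylase of the glycine cleavage system (chromosome 19, 30098447 to 30175429), rose from 0.157 ± 0.0763 to 28.4 ± 3.36 CPM (log2 fold change 7.51 ± 0.36). This was the largest rise among called genes at 5 CPM or more with no overlap of the groups, predicted names and receptor segments left out. The desmosome gene Dsp, the receptor tyrosine kinase gene Epha3 and the LIM protein gene Ajuba rose by 5.41 ± 0.26, 6.70 ± 0.35 and 5.32 ± 0.24. T-cell identity genes differed less. Of 15, 7 rose and 2 fell, with the same counts adjusted over the list alone (median 0.32, camera adjusted p = 0.0383, and adjusted p = 0.644 with an estimated correlation). The call was lost without allogeneic library 1 (camera adjusted p = 0.0723), syngeneic library 2 (0.115) or syngeneic library 3 (0.0922). Cd3e was at 675 ± 17.5 CPM in allogeneic and 443 ± 76.0 CPM in syngeneic libraries. In the CD4 lineage list 4 of 6 rose, also adjusted over the list alone (median 1.04, camera adjusted p = 0.00956, and adjusted p = 0.372 with an estimated correlation). Cd4 rose from 200 ± 35.6 to 432 ± 53.4 CPM and Cd8a fell from 591 ± 99.9 to 397 ± 38.6 CPM. In the CD8 lineage list 4 of 6 rose and 1 fell, also adjusted over the list alone (median 0.47, camera adjusted p = 0.162). In the 60 histone genes tied to DNA replication, whose reads are shared among near-identical copies, 16 rose and 2 fell, or 14 and 2 adjusted over the list alone (median 0.42, camera adjusted p = 0.00814, and adjusted p = 0.72 with an estimated correlation), a call lost without allogeneic library 1 (camera adjusted p = 0.121) or syngeneic library 1 (0.0863). Camera called 22 of the 41 lists in this comparison, 17 higher and 5 lower, and none with an estimated correlation, where 6 had an unadjusted p under 0.05 and fry called 25. The radiation dose, the T-cell dose and the recipient strain differed with the group and cannot be separated from it in any difference between the transplant groups.

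**Figure D2:**
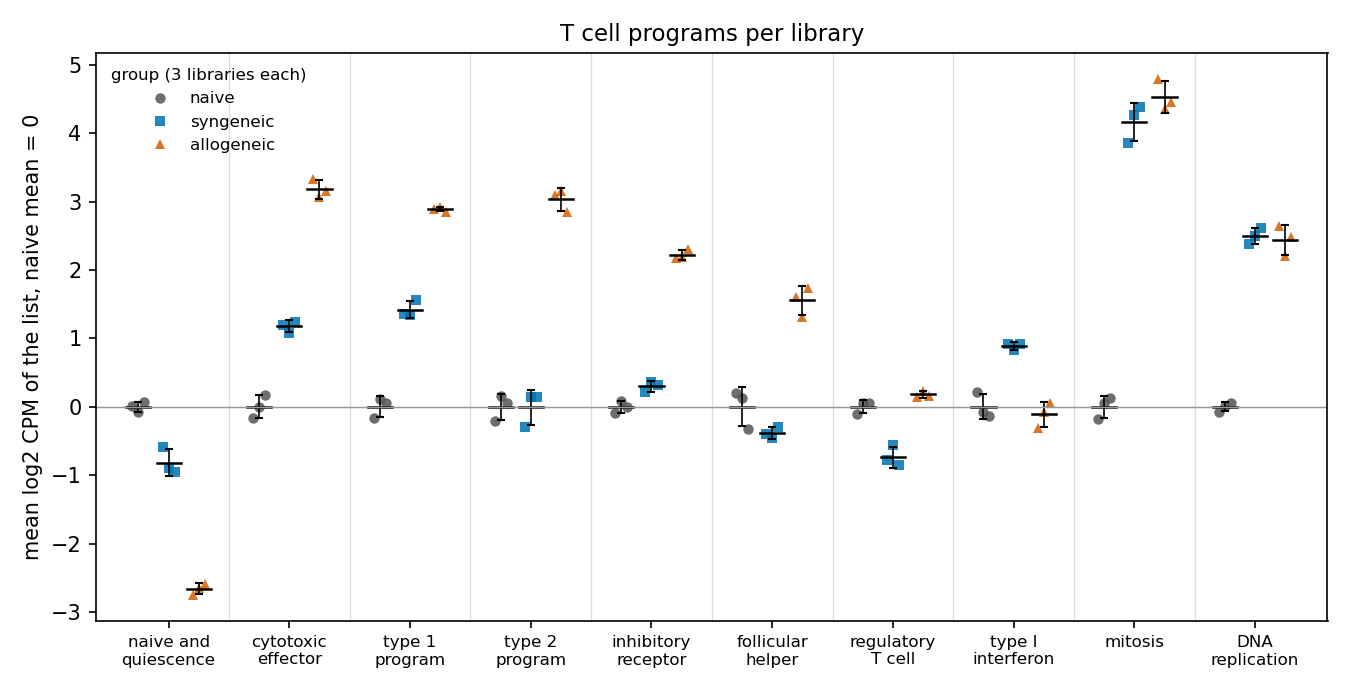
Mean log2 CPM of the genes of 10 lists fixed before the data were examined, per library and relative to the naive mean (y axis, log2 units), with naive libraries as circles, syngeneic as squares and allogeneic as triangles; black lines are the mean and SD of 3 libraries. The cytotoxic list lies at 3.18 ± 0.14 in allogeneic and 1.18 ± 0.09 in syngeneic libraries, and the naive and quiescence list at -2.66 ± 0.08 and -0.82 ± 0.19.

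The comparison of allogeneic with naive libraries asks how donor T cells had changed by day 7 in an allogeneic recipient from resting splenic T cells. Cell-cycle, cytotoxic and checkpoint genes rose and genes of the naive state fell. Gzmb rose from 4.50 ± 1.22 to 1560 ± 85.7 CPM (log2 fold change 8.45 ± 0.27, edgeR adjusted p = 1.65e-09). Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), a marker of cycling cells, rose from 44.1 ± 8.11 to 1320 ± 25.1 CPM (4.91 ± 0.23, edgeR adjusted p = 1.21e-08). Ccr7 fell from 474 ± 40.1 to 13 ± 2.05 CPM (-5.19 ± 0.18, edgeR adjusted p = 3.05e-09), and Tcf7 from 1560 ± 60.6 to 224 ± 41.2 CPM (-2.80 ± 0.16, edgeR adjusted p = 6.65e-08). Of the 19609 genes, 6229 rose and 5086 fell, 5826 of them at least 2-fold (3339 higher and 2487 lower). The groups did not overlap for 12868 genes (65.6%), where chance gives 10%.

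All 20 mitosis genes rose (median 4.73, camera adjusted p = 2.13e-13, and adjusted p = 0.357 with an estimated correlation), as did all 20 DNA replication genes (median 2.18, camera adjusted p = 3.9e-11, and adjusted p = 0.357 with an estimated correlation). Examples were the spindle checkpoint kinase gene Bub1b (4.54 ± 0.13), the mitotic kinase gene Plk1 (4.49 ± 0.16) and Rrm2, a subunit of ribonucleotide reductase (4.27 ± 0.19). Of 60 replication-dependent histone genes 56 rose and 2 fell (median 3.63, camera adjusted p = 1.57e-18, and adjusted p = 0.394 with an estimated correlation). The neutrophil and erythroid lists, which include genes of dividing precursors, rose in the same libraries, by a median of 7.67 for 15 of 15 neutrophil genes (camera adjusted p = 5.9e-08, and adjusted p = 0.357 with an estimated correlation) and 3.32 for 13 of 14 erythroid genes (camera adjusted p = 0.000326, and adjusted p = 0.575 with an estimated correlation). Ngp (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012), which encodes neutrophilic granule protein, was at 224 ± 77.4 CPM against 0.156 ± 0.0759 CPM in naive libraries. Ltf, which encodes lactoferrin, was at 139 ± 62.2 against 0.108 ± 0.0338 CPM. The counts of these lists were the same when adjusted over the list alone.

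In the cytotoxic list 15 of 17 genes rose and 1, Tnf, fell (median 2.54, camera adjusted p = 8.62e-08, and adjusted p = 0.311 with an estimated correlation). NK-cell genes, markers of another cytotoxic cell, had 8 of 11 higher and 3 lower (median 1.96, camera adjusted p = 0.0583). That p was 0.0436 without allogeneic library 3, 0.0338 without naive library 2, 0.0231 without syngeneic library 1 and 0.0494 without syngeneic library 2. In the type 1 program 17 of 18 rose and none fell (median 2.87, camera adjusted p = 3.11e-10, and adjusted p = 0.311 with an estimated correlation), with the interleukin-18 receptor genes Il18rap and Il18r1 at 3.68 ± 0.11 and 2.92 ± 0.12, Ifng at 4.28 ± 0.13 and Tbx21 at 3.06 ± 0.18. Eomes, the remaining member, was at 68.2 ± 13.9 CPM against 55.7 ± 1.27 CPM in naive libraries (edgeR adjusted p = 0.0898, and 0.0397 without allogeneic library 3). Of 17 inhibitory receptor and exhaustion genes 13 rose and 2 fell (median 1.98, camera adjusted p = 0.000149, and adjusted p = 0.311 with an estimated correlation). Pdcd1 rose by 3.86 ± 0.11, Lag3 by 4.68 ± 0.12, and Tox by 0.30 ± 0.07 (edgeR adjusted p = 0.00448, and 0.059 without allogeneic library 3). Of 10 type 2 genes 9 rose and 1 fell (median 2.81, camera adjusted p = 0.000326, and adjusted p = 0.311 with an estimated correlation). Il1rl1, the interleukin-33 receptor ST2, rose from 4.43 ± 0.928 to 117 ± 7.12 CPM. Of 9 follicular helper genes 6 rose and 2 fell (median 2.11, camera adjusted p = 0.0298, and adjusted p = 0.516 with an estimated correlation). The members that fell were Bcl6, the defining transcription factor of that lineage (-0.92 ± 0.13), and its chemokine receptor gene Cxcr5 (-0.46 ± 0.12). The homing list had 13 of 16 genes higher and 2 lower (median 1.03, camera adjusted p = 0.00107, and adjusted p = 0.311 with an estimated correlation), and the costimulation list 11 higher and 1 lower, or 13 and 1 adjusted over the list alone (median 1.04, camera adjusted p = 0.000842, and adjusted p = 0.311 with an estimated correlation). Of the 6 CD8 lineage genes 4 rose, among them Nkg7 and Ccl5 (median 0.90, camera adjusted p = 0.0446, or 0.0551 without naive library 2, and adjusted p = 0.575 with an estimated correlation). Cd8a was at 397 ± 38.6 CPM against 418 ± 34.9 CPM (edgeR adjusted p = 0.637), and Cd4 at 432 ± 53.4 against 441 ± 28.3 CPM (edgeR adjusted p = 0.863). The log2 fold change of Cd8a turned to 0.01 without allogeneic library 1, and that of Cd4 to 0.02 without allogeneic library 2 or naive library 3. The CD4 lineage list had a median of -0.06, a mean of 0.19 and a camera direction of higher (camera adjusted p = 0.783). Adjusted over the list alone, the counts of the other lists here were the same.

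In the naive and quiescence list 19 of 20 genes fell and none rose (median -2.65, camera adjusted p = 2.16e-11, and adjusted p = 0.311 with an estimated correlation). Genes of gamma delta and innate-like T cells fell, 7 of 10 with 1 higher (median -1.73, camera adjusted p = 0.0191, and adjusted p = 0.394 with an estimated correlation). Trdc, the constant region of the T-cell receptor delta chain, fell from 41.8 ± 2.82 to 2.78 ± 0.639 CPM. Zbtb16, which encodes the innate-like lineage factor PLZF, fell by 2.99 ± 0.26 on the log2 scale. The regulatory list was split, with 8 higher and 7 lower of 15 (camera adjusted p = 0.66), and Foxp3 fell from 59.8 ± 4.51 to 28.0 ± 5.39 CPM (-1.09 ± 0.14, edgeR adjusted p = 6.04e-05). Of 93 ribosomal protein genes 61 fell and 9 rose, or 63 and 10 adjusted over the list alone (median -0.56, camera adjusted p = 3.79e-05, and adjusted p = 0.614 with an estimated correlation). That list, made by name, also holds S6 kinase genes such as Rps6ka1 (0.68 ± 0.09), which are not ribosomal proteins, and processed copies of ribosomal genes can share their reads. Of 12 genes encoded by the mitochondrial genome 7 fell, or 9 adjusted over the list alone (median -0.39, camera adjusted p = 0.0472, and adjusted p = 0.6 with an estimated correlation). That call was lost without allogeneic library 1 (camera adjusted p = 0.0617), naive library 1 (0.0692) or naive library 3 (0.0726), and nuclear copies can share reads with some members. Adjusted over the list alone, the counts of the other lists here were the same.

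Glycolysis genes rose, 16 of 18 (median 1.03, camera adjusted p = 8.02e-06, and adjusted p = 0.391 with an estimated correlation), with Hk2 from 4.64 ± 0.0917 to 48.1 ± 4.84 CPM and Gapdh at a log2 fold change of 1.74 ± 0.12. Of 24 oxidative phosphorylation genes 23 rose, or 24 adjusted over the list alone (median 0.64, camera adjusted p = 2.98e-05, and adjusted p = 0.584 with an estimated correlation). Of 18 genes each, 14 of the TCA cycle rose and 1 fell (median 0.45, camera adjusted p = 0.00989, and adjusted p = 0.6 with an estimated correlation), and 13 of fatty acid oxidation rose and 1 fell (median 0.64, camera adjusted p = 0.00242, and adjusted p = 0.535 with an estimated correlation). Of 15 one-carbon and amino acid supply genes 12 rose (median 0.58, camera adjusted p = 0.00394, and adjusted p = 0.575 with an estimated correlation), with the serine synthesis gene Psat1 at 1.83 ± 0.15. Type I interferon response genes were split, 6 higher and 8 lower of 23, with a median of 0.02, a mean of -0.11 and a camera direction of lower (camera adjusted p = 0.625). That median was -0.01 with library sizes alone as scaling. Other cell-type lists also rose. Macrophage and monocyte genes had 12 of 15 higher and 1 lower (median 3.74, camera adjusted p = 0.000572, and adjusted p = 0.516 with an estimated correlation), with Lyz2, which encodes lysozyme, at 36.3 ± 17.2 against 0.341 ± 0.247 CPM. Plasma cell genes had 6 of 7 higher (median 3.32, camera adjusted p = 0.00269, and adjusted p = 0.357 with an estimated correlation), with the immunoglobulin joining chain gene Jchain at 41.8 ± 11.6 against 1.35 ± 0.766 CPM. B-cell genes had 11 of 15 higher and 2 lower (median 2.25, camera adjusted p = 0.0339, and adjusted p = 0.585 with an estimated correlation). Genes of stroma and endothelium had a median of 0.13, a mean of -0.02 and a camera direction of lower (camera adjusted p = 0.903). Outside these lists, the macrophage and neutrophil lectin gene Chil3 rose from 0.0368 ± 0.0176 to 89.9 ± 18.1 CPM, and the sialyltransferase gene St8sia6 fell from 75.1 ± 9.80 to 0.927 ± 0.308 CPM. Camera called 25 of the 41 lists, 21 higher and 4 lower, and none with an estimated correlation, where 5 had an unadjusted p under 0.05 and fry called 34. Naive mice had neither irradiation nor transfer, so that this comparison and the next hold both.

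The comparison of syngeneic with naive libraries asks what transfer and expansion in an irradiated recipient changed without a foreign antigen. Cell-cycle genes rose, and genes of erythroid, granulocytic and macrophage cells were far above the naive level. The cytotoxic and type 1 lists rose by smaller medians than in allogeneic libraries, although their members Gzmm, Tnf and Eomes were lower in allogeneic than in syngeneic libraries. Mki67 rose from 44.1 ± 8.11 to 1570 ± 433 CPM (log2 fold change 5.15 ± 0.23, edgeR adjusted p = 3.37e-08). Gzmb rose from 4.50 ± 1.22 to 93.4 ± 23.8 CPM (4.38 ± 0.23, edgeR adjusted p = 8.7e-08), while Prf1 was at 55.4 ± 8.62 against 56.2 ± 5.40 CPM (edgeR adjusted p = 0.911, and log2 fold changes of 0.04 without naive library 3 and 0.09 without syngeneic library 2). Tcf7 fell from 1560 ± 60.6 to 804 ± 151 CPM (-0.96 ± 0.15, edgeR adjusted p = 0.00042). Of the 19609 genes, 4386 rose and 3827 fell, 3603 of them at least 2-fold (2633 higher and 970 lower). With library sizes alone as scaling, 4100 rose and 4180 fell. The groups did not overlap for 10614 genes (54.1%), where chance gives 10%.

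All 20 mitosis genes rose (median 4.36, camera adjusted p = 1.66e-18, and adjusted p = 0.368 with an estimated correlation), and so did all 20 DNA replication genes (median 2.31, camera adjusted p = 3.58e-16, and adjusted p = 0.368 with an estimated correlation). Of 60 replication-dependent histone genes 57 rose and 1 fell (median 3.23, camera adjusted p = 2.32e-26, and adjusted p = 0.368 with an estimated correlation). The lists of blood cells that divide as they mature rose in the same libraries. All 14 erythroid genes rose (median 9.59, camera adjusted p = 8.9e-12, and adjusted p = 0.368 with an estimated correlation), with Slc4a1 (ENSMUSG00000006574, chromosome 11, 102348824 to 102366203) at 1270 ± 588 against 0.303 ± 0.0219 CPM in naive libraries. All 15 neutrophil genes rose (median 7.42, camera adjusted p = 2.96e-11, and adjusted p = 0.368 with an estimated correlation), with Ngp at 239 ± 118 against 0.156 ± 0.0759 CPM. Of 15 macrophage and monocyte genes 14 rose and 1 fell (median 6.19, camera adjusted p = 4.53e-07, and adjusted p = 0.368 with an estimated correlation), with Lyz2 at 102 ± 56.8 against 0.341 ± 0.247 CPM. Relative to the naive mean, the mean log2 CPM of the erythroid list was 8.08 in syngeneic library 1 and 9.57 and 9.32 in syngeneic libraries 2 and 3, and that of the neutrophil list 6.14 against 7.61 and 7.71. B-cell genes had 12 of 15 higher (median 3.45, camera adjusted p = 1.13e-05, and adjusted p = 0.368 with an estimated correlation), and plasma cell genes 5 of 7, or 6 adjusted over the list alone (median 2.09, camera adjusted p = 0.0118, and adjusted p = 0.37 with an estimated correlation). NK-cell genes had 7 of 11 higher and 1 lower, or 9 and 1 adjusted over the list alone (median 1.26, camera adjusted p = 0.00412, and adjusted p = 0.442 with an estimated correlation). Dendritic-cell genes had 5 of 8 higher and 1 lower, or 6 and 1 adjusted over the list alone (median 2.74, also with Clec9a, which had no count in naive libraries, at its bound, camera adjusted p = 0.0216, and adjusted p = 0.37 with an estimated correlation). Of 15 T-cell identity genes 12 fell and none rose (median -0.60, camera adjusted p = 4.43e-05, and adjusted p = 0.442 with an estimated correlation), with Cd3e at 443 ± 76.0 against 691 ± 37.0 CPM. Adjusted over the list alone, the counts of the other lists here were the same.

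**Figure D3:**
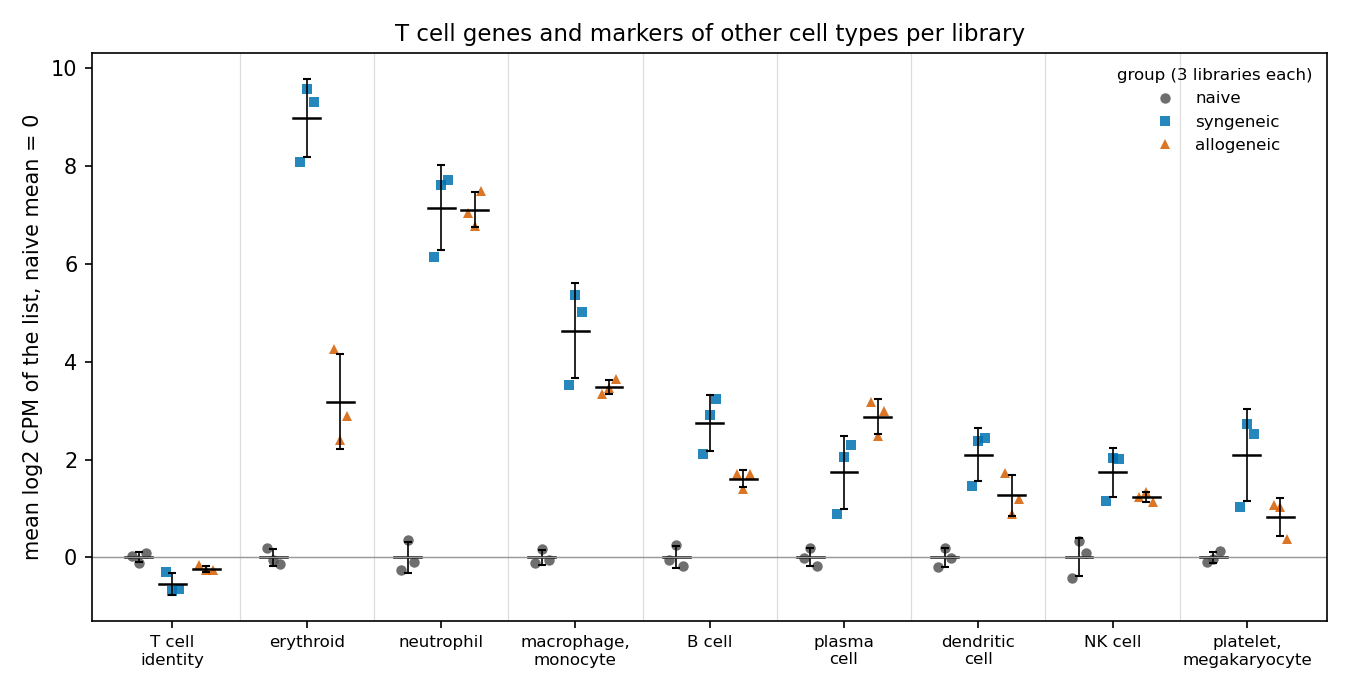
Mean log2 CPM of marker genes of T cells and of 8 other cell types, per library and relative to the naive mean (y axis, log2 units), with naive libraries as circles, syngeneic as squares and allogeneic as triangles; black lines are the mean and SD of 3 libraries. The erythroid list lies at 8.99 ± 0.80 in syngeneic and 3.18 ± 0.97 in allogeneic libraries, and the neutrophil list at 7.15 ± 0.88 and 7.10 ± 0.36.

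In the type 1 program 16 of 18 genes rose (median 1.23, camera adjusted p = 5.37e-08, and adjusted p = 0.368 with an estimated correlation), among them Tbx21 (1.49 ± 0.17) and Eomes (1.52 ± 0.14). In the cytotoxic list 10 of 17 rose (median 0.81, camera adjusted p = 6.62e-05, and adjusted p = 0.368 with an estimated correlation), with Gzmm from 5.57 ± 0.983 to 40.7 ± 4.99 CPM. The NK-cell list, markers of another cytotoxic cell, was also higher in these libraries, as given above. Inhibitory receptor genes were split, 7 higher and 5 lower of 17 (camera adjusted p = 0.879). Havcr2 and the inhibitory receptor gene Cd160 rose by 3.43 ± 0.26 and 1.47 ± 0.11, whereas Tox fell by 1.01 ± 0.08 and Pdcd1 by 0.63 ± 0.10. The naive and quiescence list had 16 of 20 genes lower and 1 higher, or 17 and 1 adjusted over the list alone (median -0.85, camera adjusted p = 8.42e-07, and adjusted p = 0.368 with an estimated correlation). Lef1, a transcription factor of naive T cells, and S1pr1, the receptor for exit from lymphoid organs, fell by 1.41 ± 0.12 and 1.26 ± 0.11, and Bcl2, a survival gene, was the member that rose (0.63 ± 0.11). In the regulatory list 10 of 15 fell and 3 rose (median -0.85, camera adjusted p = 0.00406, and adjusted p = 0.368 with an estimated correlation), with Foxp3 from 59.8 ± 4.51 to 26.9 ± 4.19 CPM. Of the 6 CD4 lineage genes 4 fell, or 5 with 1 higher adjusted over the list alone (median -0.83, camera adjusted p = 0.0121, and adjusted p = 0.368 with an estimated correlation). Cd4 fell from 441 ± 28.3 to 200 ± 35.6 CPM and Zbtb7b, the CD4 lineage factor ThPOK, by 1.29 ± 0.11 on the log2 scale. T-cell identity genes fell as well, as given above (median -0.60, 12 of 15 lower). How much of the falls of the naive, regulatory and CD4 lineage lists this accounts for was not tested. Of the 6 CD8 lineage genes 4 rose (median 0.57, camera adjusted p = 0.0261, or 0.0534 without naive library 2 and 0.0985 without syngeneic library 1, and adjusted p = 0.442 with an estimated correlation), with Cd8a from 418 ± 34.9 to 591 ± 99.9 CPM. Adjusted over the list alone, the counts of the other lists here were the same.

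Of 23 type I interferon response genes 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 2e-04, and adjusted p = 0.442 with an estimated correlation). Rsad2 rose from 6.16 ± 1.93 to 128 ± 42.0 CPM and Isg15 from 9.63 ± 1.09 to 31.4 ± 2.58 CPM. Of 20 interferon gamma response genes 9 rose and 1 fell (median 0.30, camera adjusted p = 0.0099, or 0.0985 without syngeneic library 1, and adjusted p = 0.442 with an estimated correlation). They include Irf8 and the class II transactivator gene Ciita, which B cells and macrophages express at high levels, and the B-cell and macrophage lists were higher in the same libraries. One-carbon and amino acid supply genes rose, 14 of 15 (median 0.82, camera adjusted p = 3.3e-06, and adjusted p = 0.368 with an estimated correlation), with the amino acid transporter gene Slc7a5 from 57.1 ± 3.08 to 148 ± 10.7 CPM. Glycolysis genes had 12 of 18 higher, or 13 adjusted over the list alone (median 0.54, camera adjusted p = 0.000448, and adjusted p = 0.442 with an estimated correlation). Oxidative phosphorylation genes had 13 of 24 higher, or 14 adjusted over the list alone (median 0.33, camera adjusted p = 0.00412, and adjusted p = 0.696 with an estimated correlation). Of 15 unfolded protein response genes 9 rose, or 10 adjusted over the list alone (median 0.43, camera adjusted p = 0.00756, and adjusted p = 0.431 with an estimated correlation), with the chaperone gene Hspa5 at 0.64 ± 0.11. Ribosomal protein genes had 29 of 93 lower and 5 higher, or 18 and 3 adjusted over the list alone and 53 and 2 with library sizes alone as scaling (median -0.34, camera adjusted p = 6.18e-05, and adjusted p = 0.718 with an estimated correlation). Outside the lists, Apol11b (chromosome 15, 77633946 to 77643286) stood at 79.1 ± 29.8 against 0.0028 ± 0.00484 CPM, and St8sia6 fell from 75.1 ± 9.80 to 6.72 ± 1.39 CPM. Tinagl1 had no count in naive libraries and was at 20.2 ± 10.1 CPM in syngeneic libraries, at least 2520-fold higher than a count of 3 over the naive group. Camera called 24 of the 41 lists, 19 higher and 5 lower, and none with an estimated correlation, where 3 had an unadjusted p under 0.05 and fry called 28. Lists whose median, mean and camera direction differed in sign, none of them called, were costimulation (median -0.20, mean 0.15, camera lower), fatty acid oxidation (-0.14, 0.01, lower), the type 2 program (-0.10, 0.04, lower) and cholesterol synthesis (0.04, -0.04, lower). The median of cholesterol synthesis was -0.01 with library sizes alone as scaling. Of 12 genes encoded by the mitochondrial genome none passed by edgeR's quasi-likelihood test, 2 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom called 0, with a median of -0.07, a mean of 0.00 and a camera direction of lower.

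Both transplant groups were compared with the same naive libraries, so the overlap of their changes was set beside simulated groups with no change. Genes that rose in both included the cell-cycle genes above, Gzmb, Ifng and Tbx21, and genes that fell in both included Tcf7, Ccr7 and Foxp3. In all, 3328 genes were higher and 2435 lower in both groups, or 5763 in the same direction, where lists drawn independently would share 2386. The 20 simulations without any change gave 0, but groups without change have few called genes, if any. That count therefore does not measure what the shared naive libraries add. In opposite directions, 300 genes were higher in allogeneic and lower in syngeneic libraries, and 160 the reverse, where independent lists would give 2353. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.745, against 0.501 in simulations with no change, and their covariance was 2.238 against 0.086. The 3 naive libraries were not split between the 2 comparisons, and part of the overlap may come from the shared controls.

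The balance of CD4 and CD8 coreceptor transcripts was compared per library. The Cd8a to Cd4 ratio of CPM was 0.95 in naive, 2.96 in syngeneic and 0.92 in allogeneic libraries, from log2 ratios of -0.08 ± 0.028, 1.57 ± 0.186 and -0.12 ± 0.316 (mean ± SD, n = 3). The allogeneic mean was lower than the syngeneic mean by a log2 difference of -1.685, and the syngeneic mean was above the naive mean by 1.643, each with no overlap of the groups and the smallest p that 20 arrangements of 3 against 3 libraries allow (p = 0.1 by an exact 2-sided permutation test). Allogeneic and naive libraries differed by -0.042 (exact permutation p = 1.0). The ratio is of transcripts, not of cells. With Cd8b1 in place of Cd8a, the log2 differences were -1.205 and 1.302.

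The usage of T-cell receptor beta variable segments was compared over 21 Trbv segments, each library thinned to 22104 counts, as a measure of how evenly the repertoire was spread. Shannon entropy was 3.96 ± 0.022 bits in naive, 3.98 ± 0.023 bits in syngeneic and 3.95 ± 0.07 bits in allogeneic libraries. The differences of -0.035 between allogeneic and syngeneic (exact permutation p = 0.7), -0.011 between allogeneic and naive (exact permutation p = 1.0) and 0.023 between syngeneic and naive libraries (exact permutation p = 0.4) did not separate the groups. The entropy of alpha segments did, with no overlap of any groups, at 5.67 ± 0.012 bits in naive, 5.65 ± 0.01 bits in syngeneic and 5.53 ± 0.082 bits in allogeneic libraries (exact permutation p = 0.1 for each pair). Gene counts by segment hold no clonotypes, and related segments can share reads.

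Some long noncoding RNAs differed between the groups, while their fixed list was not called in any comparison. Malat1 (ENSMUSG00000092341, chromosome 19, 5795690 to 5802672), an abundant nuclear RNA, was at 5880 ± 568 CPM in naive, 3920 ± 688 CPM in syngeneic and 2270 ± 504 CPM in allogeneic libraries. It fell in allogeneic against naive libraries by 1.37 ± 0.18 (edgeR adjusted p = 6.35e-05). Miat (ENSMUSG00000097767, chromosome 5, 112213228 to 112229395) was at 6.00 ± 3.35 CPM in allogeneic, 0.189 ± 0.0649 CPM in syngeneic and 0.300 ± 0.157 CPM in naive libraries, and rose against syngeneic libraries by 4.98 ± 0.56 (edgeR adjusted p = 3.45e-05). Gas5, a snoRNA host gene that accumulates in growth-arrested cells, was at 127 ± 8.01 CPM in syngeneic, 84.7 ± 6.42 CPM in naive and 73.3 ± 5.66 CPM in allogeneic libraries, and the microRNA host gene Mir17hg at 6.06 ± 0.941, 5.25 ± 0.869 and 1.94 ± 0.525 CPM. Redrum, a red-cell long noncoding RNA, was at 5.27 ± 3.00 CPM in syngeneic and 0.0912 ± 0.14 CPM in allogeneic libraries and moved with the erythroid list. The fixed list of 16 long noncoding RNAs had 2 higher and 6 lower in allogeneic against syngeneic libraries, also adjusted over the list alone (camera adjusted p = 0.135, and 0.399 and 0.482 in allogeneic and syngeneic against naive libraries).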

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

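All tests of explanations and the counts of other splits in this part were chosen after the results were seen.

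A set of genes moved in opposite directions against the naive libraries in the 2 transplant groups. There were 460 such genes. Of those named, Pdcd1 rose by 3.86 in allogeneic and fell by 0.63 in syngeneic libraries on the log2 scale, a difference of 4.49. The differences were 1.31 for Tox, 2.19 for Il2ra, 2.52 for Icos, 3.02 for Maf, 1.81 for Gata3, 2.92 for Nrp1 and 3.20 for Cxcr6, each higher in allogeneic and lower in syngeneic than in naive libraries. Tnfrsf9 differed by 2.06 and Epha3 by 6.70 in the same way. The log2 fold changes of these genes in syngeneic against naive libraries ran from -0.33 for Tnfrsf9 to -1.21 for Epha3. T-cell identity genes also fell in that comparison, by a median of -0.60 (12 of 15 lower, none higher). How much of these falls belongs to a general fall of T-cell transcripts was not tested. The rise of Tox in allogeneic libraries was lost without allogeneic library 3 (edgeR adjusted p = 0.059). The fall of Tnfrsf9 in syngeneic libraries was lost without any 1 of the naive or syngeneic libraries (edgeR adjusted p of 0.0579 to 0.0985). That of Epha3 was lost without naive library 3 (edgeR adjusted p = 0.0595), syngeneic library 1 (0.0519) or syngeneic library 3 (0.0712). The reverse pattern held for Myc (-1.18) and Usp18 (-2.08), and for Klra8, which had no count in allogeneic libraries, with a bound of -6.10. The call of Klra8 against naive libraries was lost without allogeneic library 2 (edgeR adjusted p = 0.0686), naive library 2 (0.0777) or naive library 3 (0.0634).

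The first pattern weighed was the erythroid signal, far higher in syngeneic than in allogeneic libraries. A lower share of T cells that raises the markers of all other cell types alike is argued against. The allogeneic minus syngeneic difference of the erythroid score lay apart from that of the neutrophil score by -5.76 log2 units, with a pooled SD of 0.72. A lower share of T cells with erythroid cells alone in their place would also give such a gap, so this comparison does not address it. Globin RNA alone is also argued against, since the other erythroid members had a median of 102 CPM in syngeneic libraries and at least 48.4 CPM in each. All 14 of 14 erythroid genes were higher in syngeneic than in naive libraries, led by Hbb-bs at 1450, Slc4a1 at 1270 and Car2 at 391 CPM. Erythroid cells in the sorted fraction would give this, although the sort for CD3 and CD45.2 and the enrichment before it should remove them. This count restates the signal and is no separate test, and 13 of 14 were also higher in allogeneic than in naive libraries. Of the 14 erythroid genes 1 reached 5 CPM in naive libraries and none is in another list. The radiation dose, T-cell dose and recipient strain remain open and untested.

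The second pattern was the rise of mitosis genes in both transplant groups, whose source may be T cells or other dividing cells. Hemoglobin-making erythroid cells as the source in allogeneic libraries are argued against, because mitosis genes differed by a median of 0.36 between allogeneic and syngeneic libraries while the erythroid score differed by -5.80. For syngeneic libraries erythroid cells remain open, since the library with the lowest erythroid score, lower by -1.36, also had a lower mitosis score, by -0.47, and 1 library decides nothing. Granulocyte precursors cannot be told apart from dividing T cells here, since the neutrophil score, too, was alike in both groups (difference of -0.05, pooled SD 0.67), with Ngp at 239 CPM in syngeneic and 224 CPM in allogeneic libraries. The sort should remove both cell types, none of the 15 neutrophil genes reached 5 CPM in naive libraries against 9 of the 20 mitosis genes, and no gene of either list is in another list.

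The third pattern was the higher level of cytotoxic, type 1 and inhibitory receptor genes in allogeneic libraries, where 41 of 51 members rose and 4 fell with a median of 1.68. Dilution of the syngeneic libraries by RNA of other cells is argued against as the whole cause, since that median exceeded the median of T-cell identity genes by 1.35 against an SD of 0.39. For a larger share of CD8 cells the values were mixed. The log2 ratio of Cd8a to Cd4 was lower in allogeneic libraries, by -1.685 with a pooled SD of 0.259, and by -1.205 with Cd8b1. A larger share would raise it, but the ratio is of transcripts, not of cells. Of the 6 CD8 lineage genes 4 rose and 1 fell (median 0.47, camera adjusted p = 0.162). Since 2 of these 6 are also in another list, their list is no separate measure of the share, which stays open. NK cells in the sorted fraction remain open, because the 11 NK-cell genes went both ways (5 higher, 4 lower, median 0.17, mean -1.07). That mean includes a fitted log2 fold change of -9.01 for Klra8, which had no count in allogeneic and 0.522 CPM in syngeneic libraries. Klrk1, Klrb1c and Itga2, which rose, can also be made by activated T cells. The sort for CD3 should remove NK cells, 2 of the 11 NK-cell genes reached 5 CPM in naive libraries and 1 is in another list, and a response to foreign antigen, the T-cell dose and the recipient strain stay open and cannot be separated in this design.

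Other splits of the libraries were set beside the counts of changed genes, with only the 6 libraries of a comparison in the fit. For each comparison 1 of the 10 splits, the real one, gave as many changed genes. The real counts were 7952 for allogeneic against syngeneic, 11135 for allogeneic against naive and 8740 for syngeneic against naive libraries, and the highest of the other splits was 0 by edgeR's quasi-likelihood test in each, with at most 731, 270 and 1157 genes at an unadjusted p under 0.05. With 10 splits a share under 0.05 cannot be reached. Each other split also put libraries of both groups on both sides, so that a large group difference enters its spread and removes calls. The counts of 0 are therefore no separate support for the real grouping.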

How the results depend on the processing

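The settings without genes under 5 CPM in naive libraries, without Gm26917 and Gm42418, and without both allogeneic library 1 and syngeneic library 1 were chosen after seeing the data. All others were planned.

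Under most settings the counts of changed genes stayed within 1.5 times of the reported ones. A minimum log2 fold change of 1, which passes fewer genes by construction, left 3816 genes in allogeneic against syngeneic, 5826 in allogeneic against naive and 3603 in syngeneic against naive libraries, and 2640 changed in the same direction in both transplant groups. With genes at 5 CPM or more in naive libraries, where fewer genes are tested, the counts were 5424, 6603 and 5284. DESeq2 gave 9129, 11565 and 8605 genes, limma-voom 8810, 11193 and 8169, the stricter filter 7418, 9309 and 7242, and the fit without allogeneic library 1 and syngeneic library 1 9045, 11339 and 9540. Leaving out each library in turn gave 6930 to 9123, 9881 to 11802 and 6347 to 9019 genes, and 4573 to 5930 in the same direction in both groups. No scaling moved the share of higher calls by over 10 percentage points. In syngeneic against naive libraries the majority turned to lower genes with library sizes alone (4100 higher, 4180 lower), with the 2 groups alone in the fit (4236, 4504) and with genes at 5 CPM or more in naive libraries (2563, 2721). At 2-fold 1533 were higher and 2283 lower in allogeneic against syngeneic libraries, where the majority also turned, and the cause was not tested.

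With an estimated inter-gene correlation camera called 0 lists in each comparison. At an unadjusted p under 0.05 there were 6, 5 and 3 lists, and fry called 25, 34 and 28. The estimates ran from -0.029 for stroma and endothelium to 0.856 for oxidative phosphorylation, with 0.79 for mitosis and 0.832 for erythroid genes. All but that of stroma and endothelium exceeded the preset of 0.01, on which the first camera p-value of each list rests. How much of the loss of calls this explains was not tested. Leaving out each library gave 20 to 23, 24 to 26 and 23 to 27 lists. The replicate numbers of the labels were tried as a replicate block, which gave 8669, 11226 and 8034 genes, 5634 shared ones and 22, 26 and 26 lists. Among the genes named it ended 2 calls, the rise of Il7r in allogeneic against syngeneic libraries (edgeR adjusted p = 0.0534) and the fall of Tnfrsf9 in syngeneic against naive libraries (edgeR adjusted p = 0.0521). The libraries share only a number. Deviations of libraries with the same number correlated at -0.118 to 0.265, and not each library correlated best with its own number, since naive library 3 did so with syngeneic library 1 (0.182, against -0.024 with its own number).

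Of 180 pairs of a named gene and a comparison, 168 kept their direction and call under each of the 20 settings that tested them. DESeq2 ended 1 call and limma-voom 3, and DESeq2 size factors, library sizes alone, no filter and leaving out Gm26917 and Gm42418 changed none. Calls of Ighm, Il7r, Tox, Epha3, Tnfrsf9 and Klra8 were lost under at least 1 setting, and Eomes and Mki67 gained one. Values that turned were not called before or after, and the cause was not tested. Foxp3 in allogeneic against syngeneic libraries turned to -0.06 with genes at 5 CPM or more in naive libraries, to -0.00 with the stricter filter, to -0.10 without allogeneic library 2 and to -0.02 without syngeneic library 1, with a range of -0.10 to 0.18 over the libraries left out. Prf1 in syngeneic against naive libraries turned to 0.04 with genes at 5 CPM or more in naive libraries, to 0.04 without naive library 3 and to 0.09 without syngeneic library 2 (range -0.13 to 0.09). In allogeneic against naive libraries Cd4 turned to 0.02 without allogeneic library 2 or naive library 3 (range -0.13 to 0.02), and Cd8a to 0.01 without allogeneic library 1, also with syngeneic library 1 left out (range -0.17 to 0.01).

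With Cd8b1 in place of Cd8a, the log2 difference of the ratio to Cd4 was -1.205 for allogeneic against syngeneic and 1.302 for syngeneic against naive libraries, the cause not tested. Leaving out each library, the Cd8a to Cd4 differences were -1.78 to -1.502, -0.137 to 0.141 for allogeneic against naive and 1.548 to 1.734. With alpha in place of beta segments, thinned to 7985 counts over 74 segments, the differences of entropy were -0.114, -0.136 and -0.022 bits, with no overlap of any groups (exact permutation p = 0.1 for each), where those of beta segments overlapped. The cause was not tested, and beta segments without each library gave -0.058 to 0.005, -0.035 to 0.029 and 0.011 to 0.034 bits. Depth limits what can be said of genes without counts in a group, such as Klra8 and Clec9a, where a fold is a lower bound.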

Other observations

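The list results of this part were planned, and the segments and Igkc were chosen after their values were seen.

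Genes of the common gamma chain cytokine receptors, which carry the signals of interleukins 2, 7 and 15, moved in both directions between the transplant groups, 10 of 17 higher and 4 lower in allogeneic libraries (median 0.40, camera adjusted p = 0.134). Il2rb, the beta chain shared by the receptors of interleukins 2 and 15, was at 344 ± 20.3 CPM in naive, 764 ± 76.3 CPM in syngeneic and 1500 ± 122 CPM in allogeneic libraries, and Cish, a feedback inhibitor that these cytokines induce, at 35.5 ± 2.13, 68.6 ± 2.88 and 137 ± 9.09 CPM. Il4ra, the interleukin-4 receptor, fell from 305 ± 50 to 137 ± 6.25 CPM (log2 fold change -1.16 ± 0.11, edgeR adjusted p = 1.32e-05). Of 15 p53 target genes 9 rose and 3 fell in allogeneic against syngeneic libraries (median 0.42, camera adjusted p = 0.148). Pmaip1, which encodes the death-promoting protein NOXA, rose from 9.47 ± 1.06 to 42.7 ± 0.535 CPM, while Sesn1 and the death receptor gene Tnfrsf10b fell by 0.95 ± 0.12 and 1.11 ± 0.12. Cdkn1a, the cell-cycle inhibitor p21, was at 0.306 ± 0.0757 CPM in naive, 5.66 ± 1.5 CPM in syngeneic and 12.7 ± 1.37 CPM in allogeneic libraries, and Psrc1 at 1.11 ± 0.203, 7.68 ± 1.7 and 9.68 ± 1.42 CPM. No difference of Psrc1 was found between the transplant groups (edgeR adjusted p = 0.199). Of 10 type 17 genes 5 rose and 2 fell in allogeneic against syngeneic libraries (median 1.25, camera adjusted p = 0.0816). Those that rose included the transcription factor genes Ahr (8.78 ± 0.996 to 77.1 ± 4.92 CPM) and Batf (28.6 ± 4.6 to 131 ± 16.2 CPM) and the cytokine gene Il21 (1.94 ± 0.625 to 9.24 ± 1.42 CPM), which other helper programs also use. The cytokine gene Il17f fell by 1.31 ± 0.28, and Cd163l1, a gene of gamma delta T cells, by 1.53 ± 0.30.

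The mean shares of some T-cell receptor beta segments lay apart between the groups, although the entropy of beta segments did not separate them. Trbv26 took 1.41 ± 0.11% of beta segment counts in naive, 1.24 ± 0.29% in syngeneic and 3.56 ± 0.10% in allogeneic libraries (mean ± SD, n = 3). Trbv29 took 4.11 ± 0.29%, 5.31 ± 0.05% and 8.57 ± 1.76%. Trbv13-2 took 14.2 ± 0.15%, 12.5 ± 0.41% and 9.65 ± 0.81%, and Trbv31 6.04 ± 0.16%, 4.33 ± 0.48% and 2.64 ± 0.83%. Trbv13-3 was spread most between the allogeneic libraries, at 8.74 ± 4.68%, against 6.56 ± 0.45% in naive and 5.55 ± 0.19% in syngeneic libraries. These segments are 5 of 21, and no share was tested. Igkc, the immunoglobulin kappa constant gene of B and plasma cells, was at 6.80 ± 3.37 CPM in naive, 152 ± 93.5 CPM in syngeneic and 404 ± 114 CPM in allogeneic libraries, and rose against naive libraries in both (log2 fold changes of 4.48 ± 0.56 and 5.90 ± 0.60, edgeR adjusted p of 7.92e-05 and 7.43e-06), as the plasma cell list did.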
